A study of Mus musculus with 4 samples.

How the data were processed

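RNA-seq libraries (4 in all) of mouse embryonic fibroblasts were compared, 2 with a control hairpin (shSCR) and 2 with a hairpin against Tdg (shTDG). Per the labels, the hairpins were delivered by lentivirus, infected cells were selected with blasticidin, and libraries were made with a strand-specific total RNA kit that removes ribosomal RNA. The labels give a replicate number to each library, but not whether replicates come from separate embryos, infections or days, and not the sequence or number of hairpins against Tdg.

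The deposited table holds raw read counts per Ensembl gene for the 4 libraries, per the file headers. It also holds the authors' normalized counts divided by gene length, and their log2 fold change, p-value and adjusted p-value from DESeq2, per the file headers. Other values than counts, as deposited by the authors, are written with decimal commas. The submitters' processing notes name CASAVA 1.8.2, TopHat2, Bowtie, HTSeq 0.5.4p3, DESeq and the mm9 build, with no role, order or settings. Whether counting used the strand is not stated, so overlapping genes and gene families with near-identical members are uncertain. The table has 24908 gene IDs, of which 22986 were matched to a gene name table; symbols were taken from the deposited table. In 903 rows all 4 libraries are at 0. No coordinates are given, since no annotation of the authors' build was used here. Every test rests on the raw counts, and the authors' own comparison is quoted only where it is named.

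Library totals were 64513182 and 58181603 counts for shSCR replicates 1 and 2, and 47445828 and 52966875 for shTDG. A count of 3, the most that a count of 0 allows, is 0.0465 to 0.0632 CPM in these libraries, for counting error only. The 10 most abundant genes took 6.1% to 6.7% of the counts. The libraries of a group were not duplicates: the chi-square per gene was 106 between the shSCR libraries and 111 between the shTDG libraries.

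Groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr and TMM scaling, with no covariate and Benjamini-Hochberg adjustment over 15817 genes. A gene passed at an adjusted p under 0.05. The SE is the absolute log2 fold change divided by the square root of the F statistic. DESeq2 1.42.0 with default settings and limma-voom (limma 3.58.1) were alternatives. DESeq2 gave an adjusted p for 15628 genes, and an adjusted p that DESeq2 left as NA was not counted.

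Gene lists were tested with camera, a preset correlation of 0.01 and lists of at least 5 genes, over 37 lists of pathways, RNA quality and other cell types, of which 36 were testable. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule names Tdg, the 10 genes with the largest change in each direction among genes that passed, up to 4 members per list that passed, and the 5 genes with the smallest p. The genes with the largest change needed a mean of 1 CPM, no overlap between groups and a named symbol; members of lists did not. If under 5 genes passed, the 10 with the smallest p per direction were named instead, and where a list had none passing, at most its 2 most expressed members. Since edgeR passed none, the rule was also applied to the DESeq2 calls, a choice made after this was seen. The text names part of the genes that the rule gives. Values of some list members are not reported here.

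On simulated counts for shTDG against shSCR over 15817 genes, edgeR recovered 38% of 2-fold and 94% of 4-fold changes, with 18 unplanted genes called. DESeq2 recovered 70% and 98%, with 70 unplanted genes called. A second simulation took its means and spread from the fit with the replicate number as a block, so that libraries shared a shift by number. There edgeR recovered 6% and 72%, with 0 unplanted, and DESeq2 67% and 99%, also with 0. edgeR with the block recovered 63% and 98% in the first simulation, with 72 unplanted, and 96% and 100% in the second, with 14. Both simulations used fitted dispersions, which are drawn towards those of other genes, so the spread may differ more between genes in the data. In the data edgeR without the block passed 0 genes, though Il33 had a log2 fold change of 3.41. The shares may therefore overstate what edgeR recovers here.

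The link between 3′ untranslated regions and fold change was examined for every 7-mer carried by at least 50 genes. GENCODE M21 transcripts were matched by gene ID, the longest 3′ region per gene was used, and the 11019 of 11663 genes with a mean of at least 2 CPM that had one of at least 50 bases were scored. The score of a 7-mer is the summed rank of the log2 fold change of its genes, freed of trends with length and GC content, in units of its chance SD. For comparisons of single libraries, log2 of CPM plus 0.25 was used. Of 20 planted 7-mers, 20 were recovered as the lowest. The scan used Python with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

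Alternatives were other scaling factors, filters and thresholds, the replicate number as a block, each library left out, and camera with an estimated correlation or fry. Others were added after the data were seen.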

Results

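RNA abundance was measured by strand-specific sequencing of total RNA, depleted of ribosomal RNA, from mouse embryonic fibroblasts. These are primary connective-tissue cells, here from C57BL/6 embryos at day 12.5 after coitus. The cells carried a lentiviral short hairpin RNA, either a control hairpin (shSCR) or a hairpin against Tdg (shTDG). Tdg encodes thymine DNA glycosylase, a base excision repair enzyme that removes thymine from G:T mismatches and some oxidised forms of 5-methylcytosine from DNA. Infected cells had been selected with blasticidin at 10 µg/ml from 24 hr after infection for 10 days. There were 2 libraries in each group. Reads assigned to genes numbered 64513182 and 58181603 in shSCR replicates 1 and 2, and 47445828 and 52966875 in shTDG replicates 1 and 2. Expression is given as CPM, the read count relative to the library total after scaling by the trimmed mean of M-values, as mean ± SD over the 2 libraries of a group. The comparison asked how RNA levels differ when Tdg is knocked down.

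The targeted gene was examined first. Tdg (ENSMUSG00000034674) stood at 52.9 and 46.6 CPM in the shSCR libraries and at 18.9 and 16.5 CPM in the shTDG libraries. These values rest on 3265, 2732, 892 and 911 reads. The log2 fold change was -1.49 (SE 0.14), and within the libraries of replicate number 1 and of number 2 Tdg was lower by 64.3% and 64.7%. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all genes gave an adjusted p of 0.267, which did not pass 0.05. DESeq2 gave an adjusted p of 4.04e-12, and the authors' deposited table lists a log2 fold change of -1.46 for Tdg. Without shTDG replicate 2 the edgeR adjusted p for Tdg was 0.0250, at a log2 fold change of -1.38.

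Besides Tdg, the genes with the smallest p were higher for Ly6a, Ppl and Ereg and lower for H2afy and Ube2v2 in shTDG. None of the 15817 genes tested passed in edgeR, so these are given by value. Ly6a, the surface antigen Sca-1, was at 11.98 ± 0.726 CPM in shSCR and 37.9 ± 0.971 CPM in shTDG (SD, n = 2), a log2 fold change of 1.66 (SE 0.11). Ppl, the desmosome-associated protein periplakin, was at 9.24 ± 1.43 and 35.0 ± 2.72 CPM. Ereg, the EGF family ligand epiregulin, was at 40.5 ± 2.60 and 89.8 ± 0.514 CPM. H2afy, which encodes the histone variant macroH2A1, was at 155 ± 7.66 CPM in shSCR and 62.3 ± 1.497 CPM in shTDG, a log2 fold change of -1.31 (SE 0.09). Ube2v2, a ubiquitin-conjugating enzyme variant, was at 63.9 ± 1.33 and 28.8 ± 0.502 CPM. Among genes meeting the naming rule, the next smallest p for higher values belonged to Slc2a13, C3, Adamtsl5, Penk, Dhrs9, Il33 and Gprc5b, with log2 fold changes from 0.91 for Gprc5b to 3.41 for Il33. For lower values they belonged to Arfip1, Ammecr1, Cyp26b1, Tmcc3, Cdkn2b, Fhl1 and Hltf. The log2 fold change of these ranged from -2.19 for Cyp26b1, an enzyme that degrades retinoic acid, to -0.80 for Hltf. Fhl1, a LIM domain protein of muscle and fibroblasts, was the most expressed of them, at 745 ± 15.2 and 369 ± 14.5 CPM.

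Across all genes, the edgeR quasi-likelihood test called 0 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.267. At an unadjusted p under 0.05 it held 1424 genes, 888 higher and 536 lower in shTDG. The limma-voom test also called 0. DESeq2 called 265 genes, 177 higher and 88 lower, and the authors' deposited table, made with DESeq2, holds 776 genes under the same threshold, 483 higher and 293 lower. Of the 265 genes, 224 are also called in the authors' deposited table. Of the genes named for a small p or a DESeq2 call, 6 are not called in the authors' deposited table: Sim2, Chac1, Nqo1, Hmox1, Lyz2 and Spp1, with adjusted p-values there from 0.130 for Chac1 to 0.595 for Hmox1. In each of the 265, both shTDG libraries lay beyond both shSCR libraries. A call with 2 libraries in each group favours such genes, so this is no separate support. Over the genes tested in edgeR, 39.5% were separated in this way. Chance gives 33.3% for 2 libraries against 2, if the libraries are interchangeable. The DESeq2 count was 71 without shSCR replicate 1, 116 without shSCR replicate 2 and 70 without shTDG replicate 2. Below, single genes are said to have risen or fallen where DESeq2 called them. On simulated independent libraries DESeq2 called 70 unplanted genes, against 18 in edgeR, so some of its calls may be false. In the simulation with a shift shared by replicate number DESeq2 called 0 unplanted genes. The labels do not say whether the replicates come from separate cultures. The p-values therefore measure only the spread between these libraries, which exceeded counting error and may be technical in part. Part of the spread followed the replicate numbers: deviations of same-numbered libraries from their group means correlated at 0.617 across genes. A test without a block counts this part as error, so the 0 calls of edgeR do not show a lack of effect. With the number as a block edgeR called 3726 genes, but the labels do not say what the numbers mark.

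Among the genes called by DESeq2, with a mean of at least 1 CPM, the largest log2 fold change belonged to Mmp13. This gene, which encodes the collagenase MMP-13, went from 0.411 ± 0.191 CPM in shSCR to 11.6 ± 9.87 CPM in shTDG (SD, n = 2), with 4.60 and 18.6 CPM in the shTDG libraries. Its DESeq2 adjusted p was 5.2e-04 at a log2 fold change of 4.82. Saa3, an acute-phase protein, Ccl20, a chemokine, and Il33, an alarmin cytokine, rose by log2 fold changes of 3.99, 3.84 and 3.42 in DESeq2. Without shTDG replicate 2, the edgeR log2 fold changes of Mmp13, Saa3 and Ccl20 were 3.50, 2.55 and 2.55. The adhesion receptor gene Selp rose by 3.34, Synpr by 3.15 and Bcl2l15 by 3.03. The serpin gene Serpinb2 went from 16.0 ± 8.15 to 127 ± 76.2 CPM. Among genes with a mean of at least 1 CPM, the largest falls were in Cyp26b1, at -2.19, and in Nrarp, an inhibitor of Notch signalling, at -2.05. Epas1, which encodes the hypoxia-inducible factor HIF-2α, followed at -1.75, then Apcdd1, an inhibitor of Wnt signalling, at -1.72 (edgeR value without shSCR replicate 1, -1.04) and Sim2 at -1.62. Tdg, Hr, H2afy, Pde8b and Trmt6 completed the 10, down to -1.24 for Trmt6. The 7-mer GCGGTGT occurs in the 3′ untranslated region of Cyp26b1, Epas1, Apcdd1, Sim2, H2afy, Trmt6, Ube2v2, Fhl1, Cdkn2b, Tmcc3, Edem1 and Lyz2, and also in that of Saa3, which rose.

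**Figure D1:**
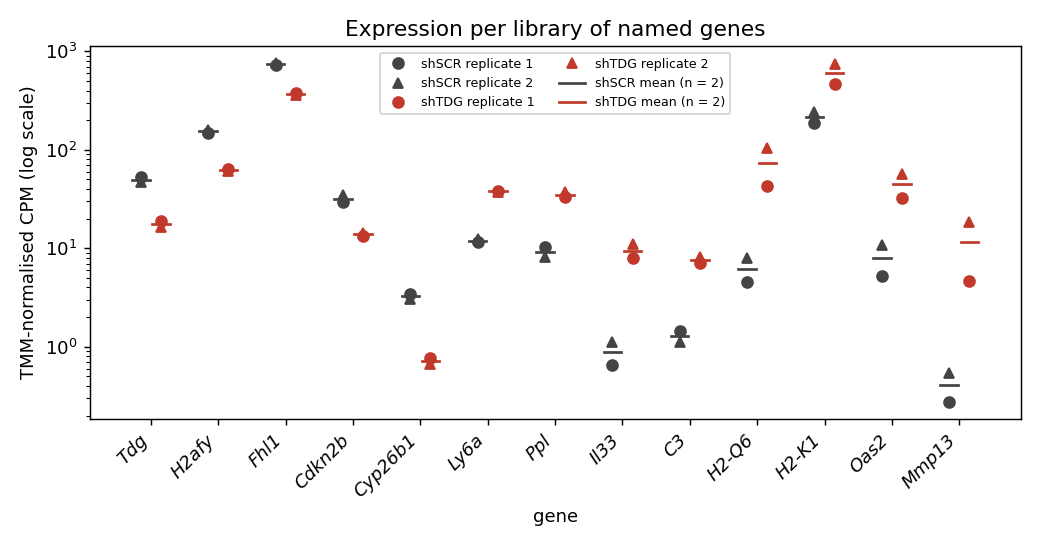
Expression per library of 13 named genes, in CPM on a log axis, with circles for replicate 1, triangles for replicate 2 and a line at each group mean (n = 2), grey for shSCR and red for shTDG. Tdg lies at 52.9 and 46.6 CPM in shSCR and at 18.9 and 16.5 CPM in shTDG, and the shTDG points of Mmp13 lie at 4.60 and 18.6 CPM.

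Interferon-stimulated genes were higher in shTDG as a group. All 36 tested members had a positive log2 fold change, with a median of 0.83, and each was higher in shTDG replicate 1 than in shSCR replicate 1 and in shTDG replicate 2 than in shSCR replicate 2. The limma camera test, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 36 lists, gave an adjusted p of 2.3e-10. The adjusted p = 0.864 with an estimated correlation, which was 0.97 for this list. That version also has few residual degrees of freedom at 4 libraries, so its lack of a call cannot decide for any list. DESeq2 called 5 members, all higher. They include Oas2 and Oasl1, of the oligoadenylate synthetase family that senses double-stranded RNA, and the antiviral gene Rsad2. Oas2 rose from 7.96 ± 3.94 to 44.5 ± 16.7 CPM (SD, n = 2), with a DESeq2 adjusted p of 5.4e-07. edgeR passed 0 members, also when adjusted over the list alone, and 8 had an unadjusted p under 0.05. The 2 libraries of a group differed by about as much as the groups: the list's median difference, replicate 2 minus replicate 1, was 0.90 in shSCR and 0.78 in shTDG. The median was 0.39 without shTDG replicate 2 and 0.45 without shSCR replicate 1, and was 1.31 without shSCR replicate 2; the camera call held in each.

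Antigen presentation genes were also higher, with a median log2 fold change of 0.92 and 14 of 14 tested members positive (camera adjusted p of 3.6e-07). The adjusted p = 0.864 with an estimated correlation. DESeq2 called 7 members, all higher, and edgeR passed 9 when adjusted over the list alone. B2m, the light chain of class I molecules, rose from 671 ± 47.7 to 1250 ± 157 CPM, with a DESeq2 adjusted p of 1.4e-04. H2-K1, a class I heavy chain, rose from 213 ± 37.6 to 601 ± 190 CPM, and the peptide transporter gene Tap1 from 55.4 ± 11.04 to 127 ± 25.4 CPM (SD, n = 2). H2-Q6 and H2-Q7 had log2 fold changes of 3.58 and 2.91 in DESeq2 (edgeR values without shTDG replicate 2, 2.81 and 2.12). They are near-identical to other class I genes, so that their counts may be shared with these and are uncertain. Summed over 16 class I H2 genes, expression was 597 and 747 CPM in shSCR and 1269 and 1952 CPM in shTDG.

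Inflammatory cytokine and chemokine genes were the group with the highest median, 0.95 over 21 tested members, 18 of them positive (camera adjusted p of 3.6e-07). Within replicate numbers 1 and 2 the median difference of this list was 0.53 and 1.38. Within number 1 the interferon and antigen presentation lists had larger medians, 0.84 and 0.84. The adjusted p = 0.864 with an estimated correlation. DESeq2 called 10 members, all higher, and edgeR passed 12 higher and 1 lower when adjusted over the list alone. Complement C3 rose from 1.29 ± 0.236 to 7.61 ± 0.842 CPM, Il33 from 0.887 ± 0.338 to 9.43 ± 2.13 CPM and the neutrophil chemokine gene Cxcl5 from 4.98 ± 0.003 to 18.7 ± 8.91 CPM (SD, n = 2). Their DESeq2 adjusted p-values were 3.3e-15, 8.0e-17 and 2.7e-05. Of the fixed macrophage marker list, 4 of 6 tested members had a positive log2 fold change, with a median of 0.14. Chosen after their values were seen, 7 macrophage genes of this list summed to 40 and 46 reads in shSCR and to 1 and 5 reads in shTDG. Lyz2, the macrophage lysozyme gene, held 25 and 30 reads in shSCR and 0 and 2 in shTDG, and was called lower by DESeq2 (adjusted p of 0.046). A count of 3 reads corresponds to 0.0632 CPM in shTDG replicate 1.

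Of the lists higher by camera, 4 further ones had smaller medians: 3 of stress responses, and the immediate-early genes, fixed as a sign of RNA quality and handling. The medians were 0.17 for the integrated stress response (22 genes, adjusted p of 0.0055) and 0.20 for the NRF2 antioxidant response (18 genes, 0.013). For p53 targets the median was 0.15 (25 genes, 0.011), and for immediate-early genes 0.15 (24 genes, 0.011). The adjusted p = 0.864 with an estimated correlation in all 4. In the order above the estimates were 0.21, 0.0073, 0.017 and -0.012, so for NRF2 and immediate-early genes they lay under the preset 0.01. For these 2 lists a larger correlation is not what took the call away. DESeq2 called Nqo1 and Hmox1, which encode antioxidant enzymes, and Klf4 and Fosl1, transcription factors of the immediate-early list. Nqo1 rose from 6.69 ± 0.477 to 15.5 ± 1.84 CPM and Hmox1 from 41.0 ± 3.07 to 93.8 ± 31.5 CPM (SD, n = 2). Klf4 rose from 8.93 ± 0.195 to 18.8 ± 0.526 CPM. Of the integrated stress response list DESeq2 called Chac1, and of the p53 list Eda2r, both higher. edgeR passed 5 NRF2 genes higher and 1 lower, and 1 immediate-early gene higher, when adjusted over each list alone, and 0 in the other 2. The camera calls of all 4 lists were lost without shTDG replicate 1, at adjusted p-values of 0.0528, 0.0534, 0.182 and 0.116 and medians of 0.21, 0.26, 0.09 and 0.13. Those of the integrated stress response, p53 and immediate-early lists were also lost without shSCR replicate 2, at 0.300, 0.116 and 0.154 and medians of 0.18, 0.14 and 0.09. That of NRF2 was lost without shSCR replicate 1, at 0.0767 and a median of 0.26. With the call kept, the median was larger by over 1.5 times without shSCR replicate 1 for the integrated stress response (0.29) and immediate-early genes (0.29). The same held without shTDG replicate 2 for p53 targets (0.24) and immediate-early genes (0.32).

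Lists lower in shTDG were led by the cytosolic ribosomal proteins, which with the abundant nuclear noncoding RNAs and the immediate-early genes make 3 of the 14 passing lists that were fixed as signs of RNA quality. The ribosomal proteins had a median log2 fold change of -0.17 and 0 of 35 positive (camera adjusted p of 5.3e-06). The adjusted p = 0.864 with an estimated correlation. Cholesterol synthesis genes had a median of -0.32, with 1 of 21 positive (adjusted p of 3.3e-04, and adjusted p = 0.864 with an estimated correlation). DESeq2 called 0 members of either list, and edgeR passed 0 of either when adjusted over the list alone. The camera calls were lost without shTDG replicate 1 for ribosomal proteins (median -0.11, adjusted p of 0.0719), and without shTDG replicate 2 for cholesterol synthesis (-0.10 and 0.119). Retroelement silencing factors, which repress transposable elements, had a median of -0.16 with 3 of 20 positive (0.0055, and adjusted p = 0.864 with an estimated correlation). Among them Trim28, the co-repressor KAP1, was at 485 ± 21.6 and 408 ± 33.1 CPM (SD, n = 2). Contractile and TGF-β response genes had a median of -0.16 (25 genes, 0.011), Hox genes -0.20 (37 genes, 0.011), abundant nuclear noncoding RNAs -0.35 (8 genes, 0.013) and cell cycle genes -0.07 (39 genes, 0.037). The adjusted p = 0.864 with an estimated correlation for these 4 lists. The most expressed contractile gene, Acta2, was at 2768 ± 594 and 2012 ± 375 CPM, and Tpm1 at 2192 ± 74.9 and 1588 ± 74.5 CPM. Malat1, the most abundant of the nuclear noncoding RNAs, was at 7289 ± 457 and 7602 ± 1037 CPM. DESeq2 called Hoxd11 and, of the cell cycle list, cyclin E1 (Ccne1) lower. The Hox and cell cycle calls were lost without shSCR replicate 2 (0.559 and 0.797) and without shTDG replicate 1 (0.825 and 0.558), where the Hox medians were 0.04 and 0.17 and those of the cell cycle genes -0.03 and -0.07. Without shSCR replicate 2 the camera direction of the Hox list was still lower, against the sign of its median. The retroelement call was also lost without these libraries, at 0.231 and 0.173 and medians of -0.10 and -0.13. Contractile genes and noncoding RNAs lost theirs without shSCR replicate 1 (0.0591 and 0.176) and without shTDG replicate 2 (0.105 and 0.258). The contractile medians were then -0.22 and -0.14 and those of the noncoding RNAs -0.11 and -0.18. With the call kept, medians were larger in size by over 1.5 times without shTDG replicate 1 for contractile genes (-0.29), without shSCR replicate 1 for cell cycle genes (-0.16) and without shTDG replicate 2 for cell cycle (-0.13) and Hox genes (-0.40). That of the ribosomal proteins was smaller without shSCR replicate 2, at -0.11 and an adjusted p of 0.04996.

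**Figure D2:**
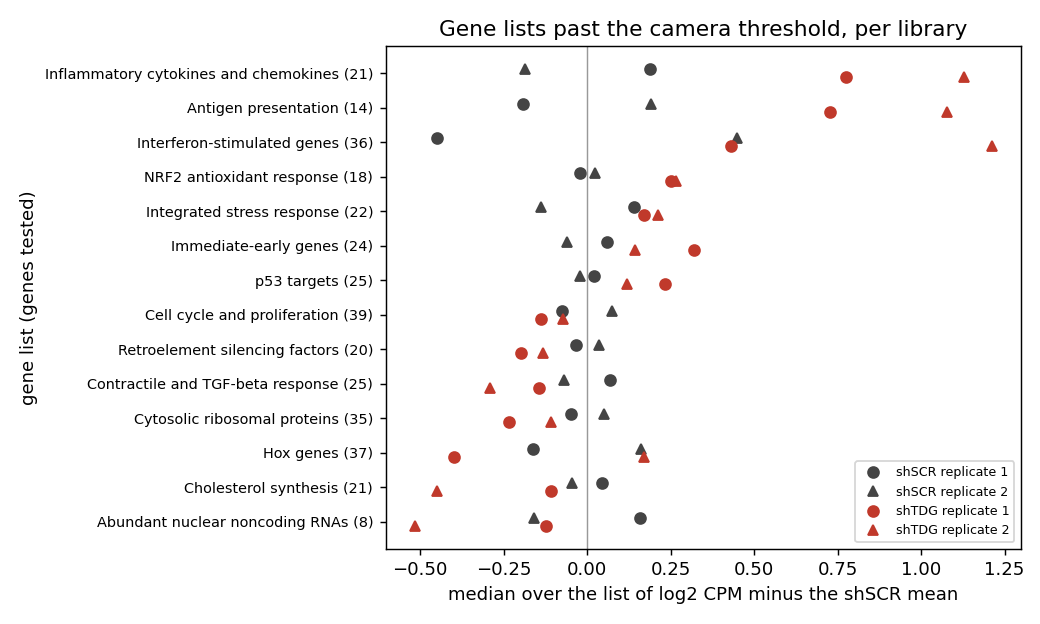
Per-library shift of the 14 gene lists that passed the camera test, as the median over each list of log2 CPM minus the shSCR mean, with circles for replicate 1, triangles for replicate 2, grey for shSCR and red for shTDG; the number of genes tested stands in brackets. Interferon-stimulated genes lie at -0.45 and 0.45 in shSCR and at 0.43 and 1.21 in shTDG.

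The 22 further lists tested did not pass camera, with adjusted p-values from 0.0537 for chondrocyte and osteoblast markers to 0.989 for other developmental transcription factors. With the replicate number as a block, camera passed the fibroblast matrix (adjusted p of 1.7e-04), chondrocyte and osteoblast (0.0062), unfolded protein response (0.011) and histone lists (0.016). The median log2 fold change of DNA demethylation and base excision repair genes was -0.04 over 27 genes, of which Tdg alone was called by DESeq2. The DNA methylation writers and readers had a median of -0.03 over 13 genes, and Dnmt1, the maintenance methyltransferase, was at 522 ± 22.6 and 518 ± 45.3 CPM (SD, n = 2). Imprinted genes had a median of -0.15 over 30 genes, and DESeq2 called 2 of them lower, Nnat and the cell cycle inhibitor Cdkn1c. Of the retinoic acid list, Rarres1 rose and Cyp26b1 and Meis2 fell in DESeq2, and edgeR passed 2 higher and 2 lower when adjusted over the list alone. In the senescence list DESeq2 called 3 higher, among them Il6 (edgeR log2 fold change 1.91, and 1.26 without shTDG replicate 2), and 1 lower, Cdkn2b, which encodes the inhibitor p15. Cdkn2b fell from 31.9 ± 3.80 to 14.0 ± 0.667 CPM, with a DESeq2 adjusted p of 6.8e-07. DESeq2 also called 3 matrix protease genes higher, Mmp13, Mmp19 and Mmp10, the matrix gene Mfap5 and the growth factor gene Vegfa higher, and Edem1, Spp1 and the Wnt gene Apcdd1 lower. Fibroblast matrix genes had a median of -0.26 over 32 genes, where the libraries of 1 group differed by -1.005 in shSCR and -1.14 in shTDG (replicate 2 minus replicate 1). Germline genes silenced by promoter methylation had 5 of 20 members above the filter and a median of -0.29. Medians of the markers of other cell types lay at 0.14 for macrophages, -0.16 for endothelium, 0.20 for epithelium, 0.22 for skeletal muscle, 0.02 for neural cells, 0.27 for adipocytes and -0.51 for chondrocytes and osteoblasts. Those of the Wnt, matrix protease, unfolded protein response and histone lists were 0.26, 0.08, -0.11 and -0.09. For heat shock and mitochondrially encoded genes they were -0.04 and -0.11, for other developmental transcription factors -0.04 and for glycolysis and hypoxia 0.00. The camera direction was opposite in sign to the median for macrophage markers, for other developmental transcription factors and for glycolysis and hypoxia. Erythroid markers were not tested as a list, since 1 of 13 passed the filter.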

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

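The tests of the DESeq2 calls, of limma-voom and DESeq2 with the block, and of the 7-mer were chosen after the results were seen; the others were planned. Against 0 genes in edgeR, DESeq2 called 265 and dropping the filter gave 12, while both other scalings, limma-voom, a mean of 1 CPM and all other thresholds gave 0. Leaving out 1 library gave 0 to 49 genes, the 49 without shTDG replicate 2; the lone library is then assumed to vary like the others. With the replicate block edgeR called 3726 genes, limma-voom 3822 and DESeq2 1812. The 265 DESeq2 genes are all among the 3726, in the same direction. The labels do not say what the replicate numbers mark. Deviations of same-numbered libraries from their group means correlated at 0.617 across genes, a hint from 2 pairs. Splitting the libraries by number instead of group gave 1 gene in edgeR and 1044 in DESeq2, and the crossed split 0 and 0, so the libraries hold a structure that follows the numbers; 3 splits are too few for a share under 0.05. For Tdg, the log2 fold change was -1.49 in DESeq2 (adjusted p of 4.0e-12), with the block (edgeR, 3.4e-08) and with no filter (edgeR, 0.033), each past the threshold, and lay between -1.60 and -1.38 with 1 library left out. Of the 63 other genes named for a small p or a DESeq2 call, all passed in DESeq2, which follows for most from how they were chosen, and with the block; 11 passed with no filter and 26 without shTDG replicate 2. The DESeq2 count was 154 at an adjusted p under 0.01, 147 at an absolute log2 fold change of at least 1, 776 in the authors' deposited table and 205 to 353 under the other settings tried. With 1 library left out it was 70 to 208, sharing 46 to 114 genes with the 265. The 14 lists became 0 with an estimated correlation and 0 by fry in 1 direction (5 lists passed fry in either direction, 2 of them among the 14), 18 with the block (interferon list, camera adjusted p of 2.9e-20), 15 at a mean of 1 CPM and 10 to 19 with 1 library left out. The median of the Hox list, -0.20, was 0.17 without shTDG replicate 1 and lay between -0.40 and 0.17 with 1 library left out. The causes were not tested, except that leaving out a library tests fewer samples. Camera with an estimated correlation also has few residual degrees of freedom at 4 libraries.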

Other observations

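The tests of the interferon genes, of the hairpin, of cultures and of Tdg loss below were chosen after the results were seen; those of base composition and the reverse complement were fixed before their own results.

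Apart from the groups, the libraries of replicate number 2 differed from those of number 1 in the same direction in both groups for several lists. Fibroblast extracellular matrix genes were lower in number 2, by a median log2 difference of -1.005 in shSCR and -1.14 in shTDG over 32 genes. The unfolded protein response chaperones differed by -0.69 and -0.65, and the mitochondrially encoded genes by -0.51 and -0.49. Replication-dependent histones were higher in number 2, by 0.32 and 0.58, and Hox genes by 0.32 and 0.48. No test was run on these differences.

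Genes lower in shTDG often carried the 7-mer GCGGTGT in their 3′ untranslated region, and of 16220 7-mers scored it had the lowest score, -10.6. The 282 genes with it had a median log2 fold change of -0.16, against -0.01 for the others. Of 84 scanned genes that DESeq2 called lower, 31 (36.9%) carried it, against 2.30% of the other scanned genes and 1 of 153 called higher. DESeq2 called 88 lower and 177 higher in all. Carriers below a mean of 2 CPM, such as Lyz2 among the lower calls and Saa3 among the higher, were not scanned. These shares are not tested, since the 7-mer was picked on the same fold changes. The lowest score in 200 shuffles of the genes was -5.15. The coding and 5′ part of the same transcripts gave -5.50. That score was freed of trends with the length and GC content of the 3′ region, not of its own sequence, so it is not strictly comparable. Base composition is argued against by the 63 7-mers of the same letters that share no 4-mer with it, whose lowest score was -2.64; TGCGGTG, of the same letters and overlapping it, had -6.92. An effect on the DNA itself is argued against by the reverse complement, at 0.32. Between the libraries of a group, replicate 2 against 1, the 7-mer scored 0.067 in shSCR and -1.36 in shTDG. These scores cannot decide on a difference between cultures, since the labels do not say whether replicates are separate cultures. A difference that coincides with the groups would also not show in them.

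What also stays open is silencing of these genes by the hairpin itself, through a short match as a microRNA has. If the hairpin strand that pairs with Tdg did this, the 7-mer would lie in the hairpin's target site. For the other strand this would not be required. GCGGTGT occurs in 6 of 11 Tdg transcripts, outside the 3′ region, and 26.2% of all 7-mers occur somewhere in a Tdg transcript. It had the lowest score in each comparison of libraries of the same number, -10.3 and -9.9997, which share no library, and -7.69 and -8.76 between libraries of different number. For H2afy, Fhl1, Cdkn2b and Cyp26b1, which carry the 7-mer, an off-target effect is a candidate explanation beside loss of Tdg. Comparing the 7-mer with the hairpin would test it, but the labels do not give the hairpin sequence. Of the 84 scanned genes called lower, 53 lack the 7-mer in their 3′ region, and Tdg, the target itself, is among them. Whether the others carry it in another part of the transcript was not counted. For these others, loss of Tdg cannot be told apart from other effects of the hairpin, since no libraries are labelled by separate hairpins.

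Interferon and antigen presentation genes were higher in shTDG. Macrophages would bring their abundant transcripts, but the 18 fixed markers found in the table, 4 of 6 tested being positive, rose in sum by 0.743 CPM, which is 0.128% of the 579 CPM rise of B2m. Reads shared between class I copies concern only the H2 genes. The other antigen presentation genes were also higher, with a median of 0.71 and 9 of 9 positive, which does not test such sharing. For the H2 genes as a whole, shared reads are argued against by the sum of these genes, which was higher in shTDG by at least 0.76 on the log2 scale. The sum cannot decide this for single members such as H2-Q6 and H2-Q7, which may take reads from more abundant ones such as H2-K1. A difference between cultures unrelated to the hairpin cannot be told apart from an effect of the hairpin or of Tdg loss. The interferon list differed by 0.90 between the shSCR and by 0.78 between the shTDG libraries, replicate 2 minus replicate 1, and within numbers 1 and 2 was higher in shTDG by 0.84 and 0.80, while the labels do not say what the numbers mark.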
